A study of Drosophila melanogaster with 2 samples.

How the data were processed

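The labels describe transcription factor ChIP-seq of whole embryos, 0 to 14 hours old and of mixed sex, from a transgenic line that stably expresses CG8290 (ADD1) with a C-terminal GFP, with chromatin sonicated to 200 to 800 bp. There were 2 biological replicates (2 and 3) in 1 group. The labels' free description calls both samples input controls, while their antibody label names CG8290. No input or GFP-only sample was analysed here, so signal shared with untagged chromatin, such as open promoters, could not be subtracted.

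The authors deposited 4 lists of regions in the narrowPeak layout with dm6 coordinates: 30000 regions for each replicate, 30000 for both replicates pooled, and the optimal IDR-thresholded peaks. Per the labels and the deposited text, regions are peaks and background prepared as input for IDR, and both replicate lists derive from the replicate's own alignments and a further file shared by both, whose role that text does not state. The aligner, the caller and the IDR cutoff are not given in the sources used here. The signal in each list is the authors' caller's value per region on an unstated scale, used only to rank or describe regions within a list. The deposited −log10 of the q-value was saturated, with 1690 of 2478 optimal peaks at the highest value of 3.53, and was not used for ranking. No p-value was given in the deposited lists. The optimal list was the 2478 regions of highest signal in the pooled list (lowest 132.9, median 183.7). It held 2471 distinct intervals, since some intervals have more than 1 summit, and widths of 111 to 983 bp, with 2097 peaks of 444 bp. No region was identical between the replicate lists. Read depth is unknown, so intervals cover the counting of peaks or genes only.

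Peak positions were compared with Ensembl release 115 gene models and the RefSeq sequence of the dm6 assembly. Transposable elements (5889 annotated) were left out of the start sites, which left 18277 genes. A summit was at a promoter within 500 bp of any start site; otherwise it took the first class of 5′ untranslated region, coding exon, 3′ untranslated region, other exon, intron and intergenic. Pericentric regions were 2L from 22 Mb, 2R to 5.6 Mb, 3L from 23 Mb, 3R to 4.2 Mb and X from 22 Mb. The background was the 26707 pooled regions that overlap no optimal peak. Shares have 95% exact (Clopper-Pearson) intervals, and shares were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment at 0.05 within each family (7 classes, 6 chromosomes, 29 gene lists, 18 motifs). Replicate overlap used each replicate's 2478 strongest regions, 1 bp of overlap and 1000 random placements within chromosomes. The signal of promoter and other peaks was compared by a permutation test of medians with 100000 resamples. Motifs were searched on both strands within 100 bp of summits, against candidate regions drawn 1:1 and matched on chromosome class, promoter status and GC content in bins of 5 percentage points.

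Before the data were examined, 30 gene lists and 18 motifs were fixed. The lists were heterochromatin proteins, homeotic, segmentation and dorsoventral genes, Polycomb and trithorax proteins, insulator proteins, cytosolic ribosomal proteins, translation factors, proteasome, DNA replication, cell cycle, replication-dependent histones, heat shock, dosage compensation, maternal and germline, zygotic activation, neuronal, muscle, gut with fat body and hemocyte, and epidermis with trachea markers, odorant and gustatory receptors, male accessory gland and testis genes, cuticle and chorion genes, heterochromatic genes, chromosome 4 genes, and tRNA, snRNA, snoRNA and rRNA genes. The list of microRNA precursors matched no gene type of the annotation and was not tested. The list of heterochromatic genes includes genes of the Y chromosome, where the optimal list has no peak. The text names ADD1, Su(var)205, XNP and w, the genes at the 25 strongest peaks, up to 4 members of each list with the highest signal and up to 3 without a peak in alphabetical order, the strongest peak of each chromosome, and the gene with the most peaks in its body.

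Alternatives fixed beforehand were the stronger 1239 peaks, each replicate's own list, peaks among the strongest regions of both replicates, other overlap rules, other windows around start sites and summits, other pericentric boundaries, and other backgrounds. Other alternatives were chosen after seeing the data. Gene lists were tested within groups by number of start sites, capped so that the top group pools unequal numbers. They were also tested among genes with any pooled region within 500 bp of a start site. Pericentric shares were compared at promoters and elsewhere, and in regions without transposable elements and with under 25% masked bases. The motif background was drawn 20 further times. The ratio of the promoter and other pericentric odds ratios and the motif tests by place, with Zelen's exact test of equal odds ratios adjusted over 18 motifs, were also added then. The computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1. The list and motif tests were tested on simulated data. Simulated lists of 20, 50 and 100 genes out of 13968 with a true odds ratio of 3 passed an unadjusted threshold of 0.05 in 56%, 84% and 100% of 50 draws, and lists with a true odds ratio of 1 in 0%, 2% and 4%. In 2000 unchanged candidate regions 0 of 18 motifs were called, and with the DRE planted in 5% of them 1 was. These settings differ from the data. Simulated genes received peaks independently, and the 2000 regions were a random part of the candidates, matched without promoter status. The simulations therefore do not show that false calls are controlled in the real comparisons.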

Results

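Binding of ADD1 to chromatin was measured by ChIP-seq in whole Drosophila melanogaster embryos collected 0 to 14 hours after egg laying, males and females mixed. ADD1 (also called CG8290) is an ADD-domain protein known as a partner of heterochromatin protein 1, and the line stably expressed it with GFP at its C terminus. The data form 1 group of 2 biological replicates, numbered 2 and 3 in the labels, and no control sample was analysed here. A description in the labels of both samples calls them input controls, while their antibody and assay labels name a ChIP of CG8290; the values were treated as ChIP. Read depth is unknown, because the deposited lists hold regions and no read counts. The authors' final list, the optimal IDR-thresholded peaks (IDR, irreproducible discovery rate, a measure of reproducibility between replicates), held 2478 peaks. These were the 2478 regions of highest signal in the pooled list, so single peaks need not be reproducible. Of them, 3 overlapped no region in the list of replicate 2, and 1 overlapped none in that of replicate 3. Each of the other lists, for replicate 2, replicate 3 and both pooled, held 30000 regions ranked by the authors' caller, peaks and background together.

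The strongest peaks stood at the same places in both replicates. The strongest peak, at X 21349714 to 21350533 (dm6), lay between the divergent genes peng and sol, 96 bp from the start of sol, and ranked 1 in each replicate with a signal of 2232 in the pooled list. The peak with rank 2 (signal 1586) lay at 2R 11969966 to 11970948, between PI31, a regulator of the proteasome, and ADD1 itself, the gene of the tagged protein (FBgn0026573, 2R 11970686 to 11977721, plus strand), and ranked 2 in replicate 2 and 3 in replicate 3. The same interval held another summit of rank 14 at position 11970553, with a signal of 873. Within 10 kb of ADD1 the pooled list held 24 regions, against a median of 10 in windows of the same width at other genes with a promoter peak. The difference was smaller in the replicate lists, with 16 against 9 in replicate 2 and 17 against 11 in replicate 3. The third peak (2R 6985606 to 6986166, signal 1581) lay at the start sites of CG17002, CG30156 and vimar, and the fourth (2L 14023895 to 14024294, signal 1396) at that of lncRNA:CR31840. Signal is the authors' own value per peak, on a scale not given in the sources used here, and is used only to rank and describe peaks within a list.

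Of the 25 strongest peaks, 15 lay within 500 bp of a start site and 6 in introns. Promoter peaks among them were at px, a gene of wing vein patterning (signal 1139), CG14100 (1120, the strongest on 3L), T48 and ro, which act in gastrulation and in eye development (1066, the strongest on 3R), CG1888 (904), NTPase and lilli (874), CG10479 (872), eag and CG9030 (865), lncRNA:CR44339 (855), mRpS10 and Art3 (831) and lncRNA:CR31044 (811). Intronic peaks lay in sbb (1061), in cno, which encodes an adherens junction protein (928), in CG11050 (894), myd (842), Lpin (831) and Tlk (803). Intergenic peaks lay 5545 bp from CG9380 at 2R 25182969 to 25183532 (1237), near lncRNA:CR44761 (866), near zfh2 on chromosome 4 at 497749 to 498067 (837, the strongest there) and near CycB (823). All 25 ranked within the first 41 regions of replicate 2 and the first 36 of replicate 3. The transcribed region with the most optimal peaks was lncRNA:CR44357 on X (7166451 to 7405797), with 11. It spans 239347 bp, and these counts were not adjusted for length.

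**Figure D1:**
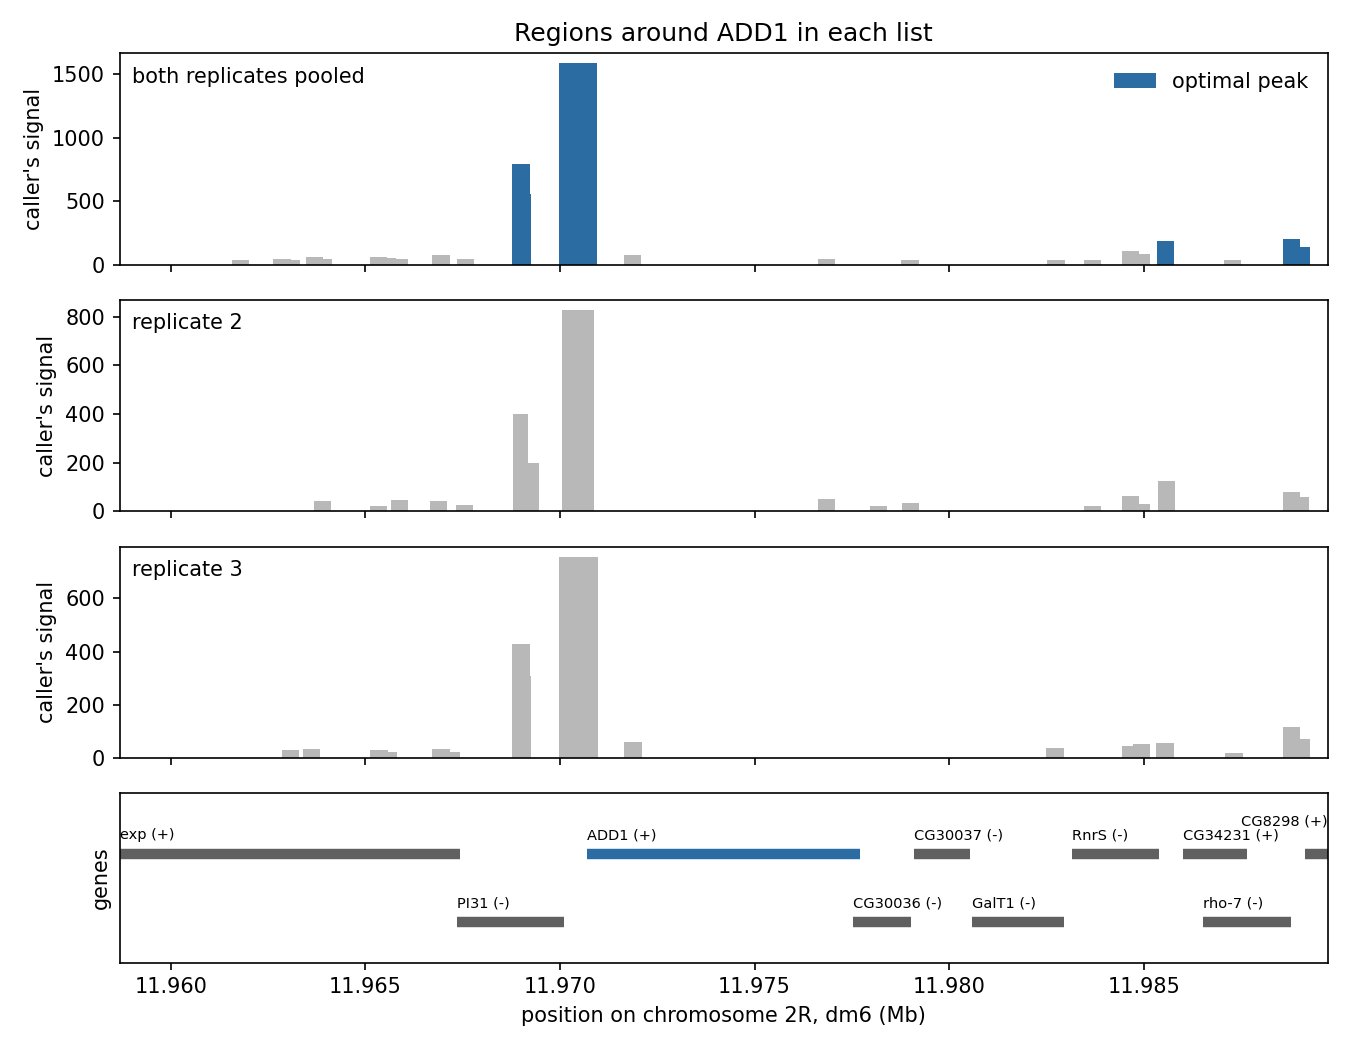
Regions of each list around ADD1 on chromosome 2R (dm6 position in Mb) against the authors' signal per region, with genes drawn as bars (strand in brackets); blue bars in the upper panel are optimal peaks and grey bars other regions. The interval between PI31 and ADD1 has the highest signal of the window in the pooled list (1586) and in replicates 2 (828) and 3 (756).

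Across the whole optimal list, 84.8% of peaks (2102 of 2478, 95% exact binomial interval 83.4 to 86.2) overlapped one of the 2478 strongest regions of replicate 2, and 82.8% (2053, 81.3 to 84.3) one of those of replicate 3. Randomly placed peaks overlapped them in 1.5% and 1.52% of cases, and at most in 2.26% and 2.30% over 1000 placements. Among the strongest regions of both replicates were 1709 peaks (69.0%, 67.1 to 70.8). Positions in the replicates' lists of 30000 regions correlated across 2474 peaks with a Spearman coefficient of 0.555 (bootstrap interval 0.522 to 0.586) and a Pearson coefficient, on the list positions themselves, of 0.193. Peaks are not independent replicates, and the optimal list was selected with both replicates, so the overlap is not an independent check.

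Peaks lay at start sites more often than other candidate regions did. Summits within 500 bp of a start site made up 57.9% of optimal peaks (1434, 95% interval 55.9 to 59.8; 44.7% within 200 bp), against 26.8% of the 26707 other candidate regions of the pooled list, and 57.6% ± 2.14 (SD, n = 2) of the strongest regions of the replicates (56.1% and 59.2%). Introns held 27.3% against 39.9%, intergenic sequence 10.3% against 20.7%, coding exons 0.646% against 7.66% and 3′ untranslated regions 1.78% against 2.97%. Shares of 5′ untranslated regions (0.969% and 0.977%) and other exons (1.13% and 0.959%) were not told apart. Fisher's exact test, two-sided, gave an odds ratio of 3.74 for promoters (p = 2.14e-208), 0.566 for introns, 0.440 for intergenic sequence, 0.0784 for coding exons and 0.591 for 3′ untranslated regions, all past the Benjamini-Hochberg threshold over 7 classes (highest adjusted p of these 0.000569). Candidate regions come from the same ranked list, so the tests set the strongest regions against weaker ones. Promoter peaks were not detectably stronger than the others, with a median signal of 184 against 183. The difference was 1.55 (bootstrap interval -5.46 to 7.12, permutation test, two-sided, p = 0.764), and its sign turned with a window of 200 bp (-5.28, permutation p = 0.115). The strongest regions of replicate 2 alone gave 4.2 (permutation p = 0.0141) in that list's own signal, which runs lower (from 67.3, against 132.9 in the optimal list).

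**Figure D2:**
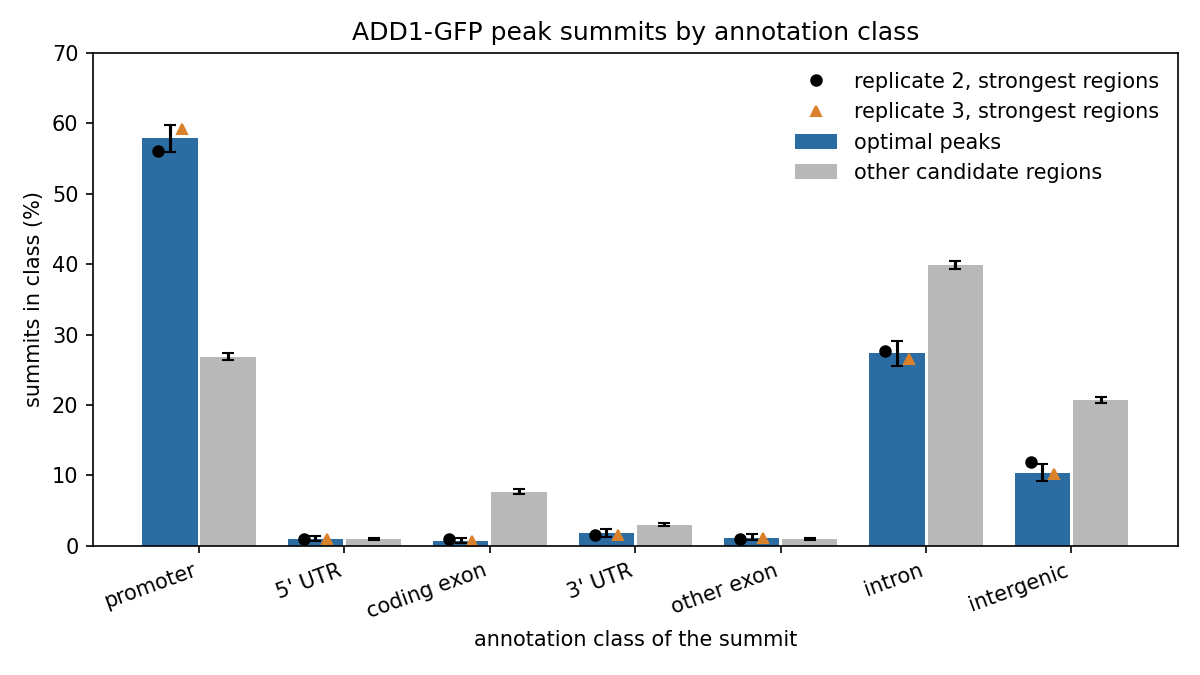
Share of summits (%) in each annotation class for optimal peaks (blue) and other candidate regions (grey), with 95% exact binomial intervals, and for the strongest regions of replicate 2 (circles) and replicate 3 (triangles). Promoters hold 57.9% of optimal peaks and 26.8% of the other candidate regions.

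Few peaks lay in pericentric regions, the gene-poor, repeat-rich sequence next to the centromeres. These regions span 18.0 Mb (13.4% of the chromosomes compared) and held 44 optimal peaks (1.78%, 95% interval 1.29 to 2.38), against 2971 other candidate regions (11.1%). By arm, 5 of the peaks lay on 2L, 18 on 2R, 16 on 3L, 4 on 3R and 1 on X. Most of the difference lay away from start sites: there 1.34% of peaks (14 of 1044) and 14.2% of candidates were pericentric, an odds ratio of 0.0821 (0.0484 to 0.139), while at promoters the shares were 2.09% (30 of 1434) and 2.75%, an odds ratio of 0.756 (0.513 to 1.12). The ratio of these odds ratios was 9.21 (95% Wald interval 4.78 to 17.7). Summits inside annotated transposable elements numbered 2 peaks (0.0807%) against 724 candidates (2.71%; Fisher's exact test, odds ratio 0.0290, p = 1.75e-25). The test over all pericentric regions gave an odds ratio of 0.144 (Fisher's exact test, two-sided, p = 3.48e-68). The share was 3.07% among the strongest regions of replicate 2 and 1.37% among those of replicate 3.

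Along the chromosomes, peak density ran from 16.9 per Mb on 3R to 34.1 per Mb on chromosome 4, with 19 on 2L, 18.1 on 2R, 19 on 3L and 19.2 on X. Chromosome 4, which is small and largely heterochromatic, held 46 peaks (1.86%) on 1.01% of the length but 2.77% of the candidates, and 3R held 543 (21.9%) against 19.6%. Fisher's exact test, with Benjamini-Hochberg adjustment over 6 chromosomes, gave an odds ratio of 0.663 for chromosome 4 and 1.15 for 3R (adjusted p = 0.0190 for both). On 2L 446 peaks, on 2R 457, on 3L 533 and on X 453 did not pass (Fisher's exact test, adjusted p from 0.0897 to 0.560). In replicate 3's own list X passed, with a lower share (17.9%) than in that list's other regions (exact test, adjusted p = 0.0109). In replicate 2's own list X held 16.9% and did not pass (exact test, adjusted p = 0.566). Each list had its own background, so these calls do not compare the replicates. The call for chromosome 4 ended in each replicate's own list (Fisher's exact test, adjusted p = 0.0526 without replicate 2 and 0.20 without replicate 3) and in peaks shared by both (0.0511); that for 3R ended without replicate 3 (0.20). Among the stronger 1239 peaks chromosome 4 held 13 (1.05%, odds ratio 0.372, Fisher's exact test, adjusted p = 4.07e-04), a density of 9.64 per Mb beside 8.76 to 9.89 on the others.

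An optimal summit lay within 500 bp of a start site of 1923 genes, among them 1754 of 13968 protein-coding genes (12.6%). Genes of cytosolic ribosomal proteins had such a peak in 52 of 93 cases (55.9%, 95% interval 45.2 to 66.2), with the strongest at RpS27 (signal 502), RpL7 (442), RpS10b (429) and RpLP0 (377); RpL10Aa, RpL10Ab and RpL21 had none. Translation factors had 14 of 52 (26.9%), led by eEF1gamma (532), eIF4EHP (471), eIF6 (339) and eIF1 (331). Insulator and boundary proteins had 8 of 14 (57.1%), led by Chro (686), Cp190 (353), Dref (314) and Ibf1 (303, a peak shared with Ibf2), whereas CTCF, BEAF-32 and dwg had none. Against other protein-coding genes the odds ratios were 9.07 (adjusted p = 4.67e-22), 2.58 (0.0118) and 9.32 (2.92e-04; Fisher's exact test, two-sided, Benjamini-Hochberg over 29 lists). Any region of the pooled list lay at a start site of 93.5%, 69.2% and 92.9% of these genes, against 48.6% to 48.9% of other genes. Among genes with such a region, a comparison chosen after seeing the data, ribosomal protein genes kept their call (59.8% against 25.2%, odds ratio 4.40, exact test, adjusted p = 5.36e-10). Insulator genes then fell short (4.65, exact test, adjusted p = 0.0509), as did translation factors (1.85, 0.333). Every optimal peak is itself a pooled region, so binding partly decides which genes enter this comparison. The comparison cannot separate binding from open promoters in general, and neither a kept nor a lost call in it decides between them. Translation factors lost their call in replicate 2's list (exact test, adjusted p = 0.118) and among the peaks shared by both replicates (0.0949).

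Genes of chromosome 4, listed heterochromatic genes, and Polycomb and trithorax group genes carried promoter peaks more often than others when all genes were compared. Pericentric regions as a whole held no larger share of promoter peaks than of candidate promoter regions (odds ratio 0.756, 0.513 to 1.12). Some of the genes are also in other lists, such as RpS3A in that of ribosomal proteins. On chromosome 4, 30 of 80 genes (37.5%, 26.9 to 49.0) had one, led by toy, an eye-specification gene (signal 338), RpS3A (324), Gyf (254) and ci (228), an odds ratio of 4.23 (Fisher's exact test, adjusted p = 1.11e-07). Of 24 genes in the heterochromatin of chromosomes 2, 3 and Y, 9 had one (37.5%), led by Dbp80 (204), Nipped-A (196), d4 (193) and Nipped-B (188), an odds ratio of 4.19 (exact test, adjusted p = 0.00447). Polycomb and trithorax group genes had 8 of 26 (30.8%, odds ratio 3.10, exact test, adjusted p = 0.0263), led by ph-p (709), brm (369), Su(z)12 (222) and pho (196). Among genes with any pooled region at a start site, a set that binding itself partly decides, the values for these 3 lists were short of the threshold: chromosome 4 genes had 40% against 25.5% (odds ratio 1.95, exact test, adjusted p = 0.0509), heterochromatic genes 52.9% against 25.6% (3.27, 0.0984) and Polycomb and trithorax genes 38.1% against 25.6% (1.79, 0.591). With the stronger 1239 peaks alone, 12.5% of chromosome 4 genes had one against 6.55% of other genes (odds ratio 2.04, exact test, adjusted p = 0.0989), and 16.7% of the heterochromatic genes against 6.57% (2.84, 0.155), short of the threshold. The heterochromatic genes also lost their call without replicate 2 (0.199) and among peaks shared by both replicates (0.273). The Polycomb call was lost without replicate 3 (exact test, adjusted p = 0.0754), with a 200 bp window (0.394) and with peaks shared by both replicates (0.0511). Within groups by capped number of start sites its odds ratio was 2.51 (1.05 to 6.00), short of the adjusted threshold.

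The genes of known heterochromatin proteins did not stand apart: 6 of 35 had a promoter peak (17.1%, 6.56 to 33.6, odds ratio 1.44, exact test, adjusted p = 0.553), led by ADD1 (signal 1586), Hers (577), sov (203) and the gene of heterochromatin protein 1, FBgn0003607 (200, rank 996 at 2L 8211074 to 8211517). XNP, the fly ATRX-type remodeller, had no region at its promoter or in its body in the optimal or pooled list, and its regions ranked 5853 in replicate 2 and 19740 in replicate 3. The pigment transporter gene w had a promoter peak of rank 319 (signal 319, X 2796456 to 2796650). It was named beforehand as a marker gene of transgenes (mini-white), and whether extra copies add to this peak was not tested.

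Lists without a call included the developmental regulators. No homeotic gene had a peak (0 of 8, upper limit 36.9%; abd-A, Abd-B and Antp among them), segmentation genes had 2 of 27 (ci and hry), dorsoventral genes 1 of 19 (vnd, 176), and markers of gut, fat body and hemocytes 1 of 19 (fkh, 519). Neuronal markers had 2 of 20 (elav 440, Appl 140), muscle markers 5 of 18 (tin 307, mbc 239) and epidermis and trachea markers 1 of 14 (trh). Proteasome genes had 6 of 32 (Prosalpha6 280), DNA replication genes 5 of 26 (dup 187), heat shock genes 5 of 20 (Hsp83 516), maternal and germline genes 5 of 19 (bgcn 251), zygotic activation genes 3 of 13 (Trl 188), dosage compensation genes 2 of 6 (msl-1 181) and snRNA genes 2 of 32 (snRNA:U5:35D 172). The noncoding lncRNA:roX1 and lncRNA:roX2 were left out of the dosage compensation test, which covered protein-coding genes, and had promoter peaks of signal 141 and 361. Cell cycle genes had 6 of 22 (aurA 234, exact test, adjusted p = 0.102), but 45.5% in replicate 3's own list (adjusted p = 4.84e-04) and 22.7% in replicate 2's. Shares of other lists differed between replicates 2 and 3 by a few genes at most, without a call in either, and the differences were not tested. They were 3.70% and 11.1% for segmentation genes, and 5.26% and 10.5% for dorsoventral genes and for gut, fat body and hemocyte markers. Neuronal markers had 5% and 10%, muscle markers 27.8% and 16.7%, and DNA replication genes 15.4% and 11.5%. Zygotic activation genes had 23.1% and 30.8%, maternal and germline genes 26.3% and 21.1%, and proteasome genes 15.6% and 18.8%. Adjusted p-values of all these lists lay between 0.102 and 1 by Fisher's exact test. In simulated lists of 20 genes a true odds ratio of 3 passed an unadjusted threshold of 0.05 in 56% of cases. Lists of this size therefore leave such higher shares open. Odds ratios below 1 were not simulated, so lower shares, such as those of homeotic genes, stay open too.

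Tissue-restricted gene families had almost no promoter peaks. Odorant and gustatory receptor genes had 0 of 179 (upper limit 2.04%, Fisher's exact test, adjusted p = 8.94e-10), male accessory gland and testis genes 0 of 65 (5.52%, adjusted p = 7.17e-04), and cuticle and chorion genes 1 of 103 (adjusted p = 1.33e-04); that gene, Cp190, encodes an insulator protein and matched the list by its symbol alone. Only 8.94%, 9.23% and 7.77% of these genes had any region of the pooled list at a start site, against 49.4%, 49.1% and 49.2% of other genes. Among genes with such a region, none of the 3 lists passed, with 0 of 16 receptor genes (exact test, adjusted p = 0.0982), 0 of 6 male genes (0.690) and 1 of 8 cuticle and chorion genes (0.918). Genes of tRNAs had 15 of 290 (5.17%, exact test, adjusted p = 1.61e-04), led by tRNA:Ala-TGC-2-1 (signal 468), and snoRNA genes 9 of 269 (3.35%, adjusted p = 2.13e-06), led by snoRNA:Or-aca5 (371). The tRNA share was 2.76% in replicate 2's own list and 6.90% in replicate 3's, and the call was kept in both. Among genes with a pooled region the tRNA call was kept (10.2% against 25.7%, exact test, adjusted p = 7.09e-05) and that of snoRNA genes was not (15.5%, 0.333). The snoRNA call also ended with a window of 1000 bp (12.6%, exact test, adjusted p = 0.648). That of male genes ended with the stronger 1239 peaks, still at 0 of 65 against 6.62% of other genes (exact test, adjusted p = 0.0565). Replication-dependent histone genes (0 of 111, exact test, adjusted p = 4.13e-06) and rRNA genes (0 of 99, 1.86e-05) also had none, but they lie in repeated arrays and only 0% and 1.01% of them had any region in the pooled list, so their binding was not assessed. Genes that share a start region share a peak, and genes can be in several lists, so p-values treat as independent what partly is not.

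**Figure D3:**
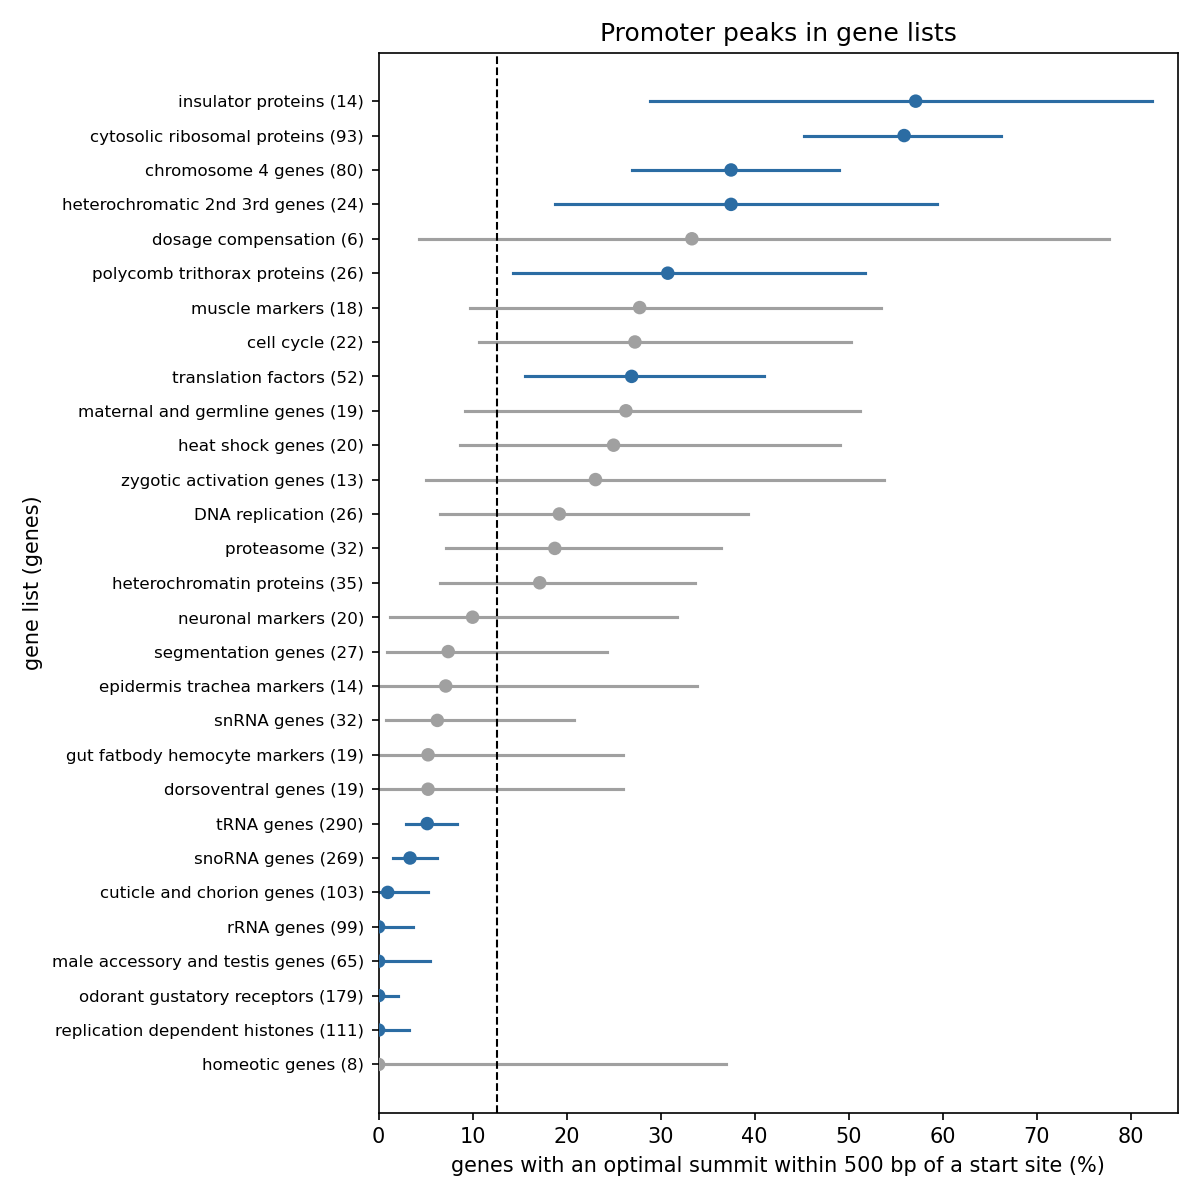
Percent of genes in each list (number of genes in brackets) with an optimal summit within 500 bp of a start site, with 95% exact binomial intervals; blue marks lists past the adjusted threshold with all genes compared and the dashed line all protein-coding genes (12.6%). Insulator and ribosomal protein genes lie highest, at 57.1% and 55.9%.

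Sequence around the summits held several motifs of insulator and promoter factors more often than candidate regions matched 1:1 on promoter status, chromosome class and GC content. The Su(Hw) site TGCATAYTTT was within 100 bp of 4.24% of summits against 1.33% (odds ratio 3.28, Fisher's exact test, adjusted p = 6.41e-09; 5.84 without replicate 2 and 3.18 without replicate 3). The GAGA repeat was at 7.75% against 4.28% (1.88, exact test, adjusted p = 2.88e-06). The BEAF core CGATA was at 32.9% against 28.0% (1.26, exact test, adjusted p = 0.00143). The DRE site TATCGATA, bound by Dref, was at 5.49% against 3.67% (1.52, 0.0104), and the CTCF core at 9.73% against 7.34% (1.36, 0.0104). CGATA lies within TATCGATA, so each summit with a DRE (136 peaks, 91 candidates) also counts for the BEAF core. The calls for both are therefore not separate, and the BEAF core outside DRE sites was not tested. A tracts were rarer, 10.7% against 13.4% (0.771, 0.0104). At promoters and away from them, the odds ratios were 2.10 and 3.53 for Su(Hw), 1.35 and 2.63 for GAGA, 1.37 and 1.08 for the BEAF core, and 1.65 and 1.76 for the DRE, which away from promoters was at only 7 peaks against 4 candidates. An exact test of equal odds ratios in both places gave adjusted p = 0.539, 0.170, 0.335 and 1 for these, and none of the 18 motifs passed. Unadjusted, the exact p was under 0.05 for GAGA (0.00946) and G quadruplexes (0.0461). The other 12 of 18 motifs did not pass (Fisher's exact test, two-sided, Benjamini-Hochberg), including Zelda (odds ratio 1.10), M1BP (1.03), Pho (1.35), the initiator (0.844) and both satellite repeats. Over 20 further draws of the matched regions, Su(Hw), GAGA, DRE and CTCF passed in 20, the BEAF core in 17 and A tracts in 12. With the stronger 1239 peaks calls were lost for DRE (odds ratio 1.41, exact test, adjusted p = 0.218), GAGA (1.46, 0.158), CTCF (1.27, 0.221) and A tracts (0.877, 0.435), while Pho passed (1.99, 0.0192). Without replicate 3 DRE (1.28) and CTCF (1.2) lost theirs (exact test, adjusted p = 0.261 for both). Among peaks shared by both replicates DRE did (1.46, exact test, adjusted p = 0.0694), while the initiator passed as rarer (0.743, 0.00711). The BEAF core lost its call with a 250 bp window (1.14, exact test, adjusted p = 0.0831) and A tracts with an unmatched background (0.985, 0.917).

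**Figure D4:**
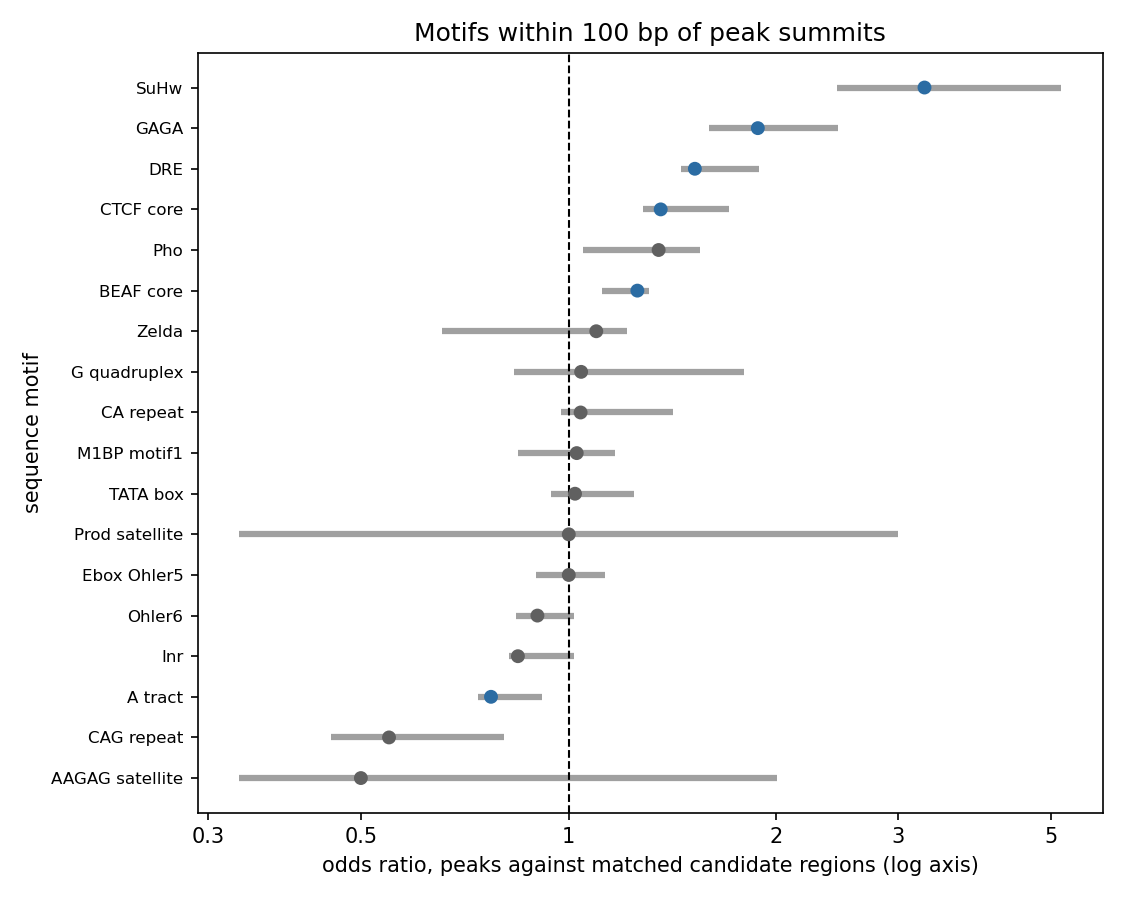
Odds ratio (log axis) of each motif within 100 bp of summits, peaks against matched candidate regions, as points (blue past the adjusted threshold), with grey bars for the range over 20 further draws of matched regions. Su(Hw) has the highest odds ratio, 3.28, with draws from 2.45 to 5.18.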

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

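Tests chosen after the results were seen were those within groups of start sites, among genes with any pooled region at a start site, of pericentric shares by class and in clean regions, and of further motif draws. Of 460 alternative values, 369 kept direction and side of the threshold or stayed within their limits, 36 became weaker, 8 stronger, 13 moved and 34 changed direction, 32 of those with neither value past the threshold. The promoter share stayed above its background and the pericentric share stayed below its background in every alternative, past the threshold except among promoters alone (odds ratio 0.756). Of 11 called gene lists with a pooled region at 5% or more of their genes (histone and rRNA genes fell below), 5 kept their call in every alternative over all genes, and 2 of these, ribosomal protein and tRNA genes, also among genes with any pooled region, a set that binding itself partly decides, where 2 of 28 lists passed and the histone list had no gene left. There, heterochromatin proteins and proteasome genes were at 24% and DNA replication genes at 25%. Of 6 called motifs 1 kept its call in every alternative, and the cause was not tested. Fewer peaks leave less power, but DRE and CTCF also lost theirs without replicate 3, where the strongest regions again numbered 2478. The peak number is 1239 in the stronger set by construction. Replicate overlap was 98.7% and 97.9% (replicates 2 and 3) for these, 77.8% and 77.3% with 50% reciprocal overlap, 98% and 97.9% with the 4956 strongest regions, and 80.5% and 78.5% with summits within 100 bp; the rank correlation with 50% reciprocal overlap was 0.449. Motifs past the threshold numbered 3 in the stronger set and 10 with an unmatched background, where GC and promoter content differ by construction. The promoter difference in signal was -1.52 in the stronger set and -5.28 with a 200 bp window. It was 1.23 to 4.2 when a replicate was left out, in the other replicate's own signal, which cannot be set beside pooled values. With the stronger set, 2R held 20.2%, cell cycle genes 4.55%, and odds ratios were 0.667 for M1BP, 0.824 for TATA, 2.00 for AAGAG and 0.635 for CA repeats. With peaks shared by both replicates, DNA replication genes were at 3.85%, M1BP at 0.826 and CA repeats at 0.774. Leaving out a replicate gave DNA replication 11.5% to 15.4%, Zelda 0.963 to 1.13, AAGAG 1.5 to 2.00, M1BP 0.984 to 1.3, Ohler motif 6 0.902 to 1.13 and G quadruplexes 0.748 to 1.08. Zygotic activation genes were at 7.69% with a 200 bp window, and neuronal markers at 15% with a 1000 bp window and with any overlap. With a 50 bp motif window the odds ratios were 1.16 for Ohler motif 6, 2.00 for AAGAG and 0.863 for CA repeats; with 250 bp they were 0.973 for M1BP, 0.985 for Zelda, 0.975 for Pho and 0.871 for G quadruplexes. The unmatched background gave calls to M1BP (1.98), TATA (1.3) and CAG repeats (0.425), and 1.38 for Ohler motif 6 (exact test, adjusted p = 4.52e-04), 0.718 for Zelda and 0.587 for G quadruplexes (0.0181). No paired analysis was possible because there is 1 group. Every alternative fixed beforehand was run; unknown read depth and 2 replicates limit every comparison.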

Other observations

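Tests chosen only after the result was seen were the ADD1 tests with strong regions kept and of the number of regions, the pericentric odds ratios by class, combined over classes and in regions without transposable elements, the tests of chromosome 4 genes within groups of start sites and among genes with any pooled region, and the divergent-pair test among regions with start sites of 2 or more genes. Promoter peaks often lay between divergent genes, as at peng and sol, PI31 and ADD1, and T48 and ro. A divergent pair had both starts within 500 bp of 567 of 1434 promoter peaks (39.5%, 37.0 to 42.1), against 19.2% of candidate promoter regions, an odds ratio of 2.76 (2.44 to 3.11). The first test set for denser start sites asked only whether this odds ratio left the range around 1, and it could not separate density from orientation, since 43.9% of peaks and 24.0% of candidates had starts of 2 or more genes in the window. Among those regions, in a test then chosen for this reason, 90.1% against 79.8% were divergent, an odds ratio of 2.31 (1.73 to 3.08), so the density of start sites alone may not account for the pattern; the distance of summits from start sites was not matched.

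A hypothesis was that a shared short sequence marks peaks on all chromosomes. Of 1825 7-mers that were at 20 or more peaks on chromosomes 2 and 4 and at a higher share of peaks than of matched candidates, the top 10 were tested on 3 and X against matched candidates, and 4 passed the adjusted threshold where all 10 were predicted if the hypothesis held and at most 2 if not. AAGTATG (odds ratio 2.86, 9.81% against 3.66% of summits) and AGTATGC (4.0, 9.03% against 2.42%) lie on the other strand of the Su(Hw) site, AGTGTGC had 1.62 and AGTGTTG 1.54. These 7-mers were chosen by the test on chromosomes 2 and 4, not by the naming rule, and the outcome lies between the predictions, so it stays open.

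The strong peak at the ADD1 promoter could come from extra copies of the gene in the tagged line. The 18 candidate regions within 10 kb of ADD1 had a median signal at percentile 36.3 of the pooled list, and all 21 regions outside the promoter peaks one at 42.1, where above 90 was predicted for extra copies; the strongest of the 21, named after their values were seen, had signals of 789 and 554 and start at 2R 11968765. These medians do not decide, although low values had been set to count against extra copies: leaving out strong regions caps the first at 91.7, and extra copies would also bring weak background into the list at low percentiles. The window held 24 pooled regions, against a median of 10 at 1753 other genes with a promoter peak (percentile 98.9), and 16 and 17 in replicates 2 and 3 (percentiles 92.2 and 85.6), short of the 95 set for all lists. Extra copies therefore stay open, as do reads from the tag construct and a signal from open promoters, and no biological explanation was tested, since the design has 1 group.

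The low share of peaks in pericentric regions might reflect fewer start sites or repeated sequence. With promoters and other regions compared separately and combined, the common odds ratio was 0.209. Among regions free of annotated transposable elements and with few masked bases the odds ratio was 0.122. These values argue against start sites within 500 bp, and against such repeats, as the whole cause. The combined value hides a difference between classes. Away from start sites the odds ratio was 0.0821, which argues against start sites within 500 bp as the cause there. Distance beyond 500 bp was not matched, so fewer start sites farther off stay open. At promoters the odds ratio was 0.756 and its interval spans 1. A lower share of pericentric promoters therefore cannot be told apart from none at this number of peaks. Broad, low enrichment that a caller of narrow peaks ranks low, and the ranking of background regions in repeats, were not tested. No biological explanation was tested.

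The higher share of chromosome 4 genes with a promoter peak might come from more start sites per gene. Within groups of genes with equal numbers of start sites the common odds ratio was 3.32 (2.08 to 5.31), which argues against that as the whole cause. With the stronger 1239 peaks the share was 12.5% against 6.55% of other genes (odds ratio 2.04, exact test, adjusted p = 0.0989), short of the threshold. The odds ratio was also lower than the 4.23 with all peaks. The stronger peaks are part of all peaks, and the difference between these odds ratios was not tested. Among genes of chromosome 4, 93.8% had some region in the pooled list, against 48.7% of other genes, and among genes with one the shares were 40% and 25.5% (odds ratio 1.95, exact test, adjusted p = 0.0509). Every optimal peak is itself a pooled region, so this comparison cannot separate binding from open promoters in general, which stay open, and no biological explanation was tested.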
